A study of Homo sapiens with 12 samples.

How the data were processed

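The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) for histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers. The cells were KOLF2.1J, an established human reference line of induced pluripotent stem cells (iPSCs), with a transgene of inducible transcription factors inserted at the CLYBL gene. Per the labels, 3 conditions were profiled: untreated iPSCs, untreated microglia at day 18 of differentiation, and day 18 microglia treated for 24 h with lipopolysaccharide (LPS, a bacterial activator of Toll-like receptor 4) and interferon gamma (IFNG) at 20 ng/ml. The LPS dose is 100 ng/ml in the treatment field and the series design, which was used here, while the sample titles print mg in place of ng. Each condition had 2 immunoprecipitated and 2 input samples, 12 samples in all. Libraries were amplified with 15 PCR cycles, per the labels' protocols.

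The values come from 3 peak lists, 1 per condition. The submitters' processing notes name the hg38 build and the tools Trimmomatic, Bowtie2, Picard and MACS2, without versions. The names of the deposited lists describe optimal sets of overlapping peaks, without saying how these were made. The peaks number 46.6%, 86.9% and 90.0% of the highest number in the peak names of the iPSC, microglia and stimulated lists. The use of the inputs and the thresholds are not given in the sources used here. The lists have no header and follow the narrowPeak layout of 10 columns, so the meaning of each column is taken from that layout. Each peak carries a fold over background, a ratio given by the authors' peak caller. The deposited lists also give −log10 p and −log10 q for each peak. These per-peak values belong to the authors and are used to describe, rank or filter peaks within a list, except for a ratio of −log10 p between lists in the closing section. Read depth per sample is unknown from these files, so no interval resting on depth can be given. Because a condition has 1 list, no value has a replicate error, no p-value is given, and a difference between lists compares lists and has no replicate check.

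Peaks on chromosomes 1 to 22 and X were used and those on other sequences were left out. Overlapping intervals within a list were merged. Peaks of a pair of lists were called shared when they overlapped by at least 1 bp, and the overlap expected by chance was taken from 100 circular shifts of a list along each chromosome. Genes were the 19974 protein-coding genes of the RefSeq table for GRCh38.p14 on these chromosomes. That table gives the start and end of each gene and no strand. Gene ends were therefore used where transcription start sites had been planned: a gene had a peak at a gene end when a merged peak lay within 1 kb of either end. Exons, introns and untranslated regions were not annotated for the same reason.

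Covered length was the number of base pairs under merged peaks in the gene body plus 10 kb on each side. A gene was measured when at least 1000 bp were covered in either list. It was called longer or shorter when log2((b + 500)/(a + 500)), with b and a the covered lengths in bp of the later and the earlier condition, was at least 1 in size and the lengths differed by at least 1000 bp. A log2 ratio of covered length is on this scale, which understates the change of genes with little cover. Longer and shorter refer to called peak intervals and not to the height of the signal. Windows of neighbouring genes overlap, so a peak can count for several genes.

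The 23 gene lists, with 538 entries of which 535 were in the gene table, were fixed before the data were examined, as were the comparisons, thresholds and alternatives except where stated. They cover pluripotency, myeloid transcription factors, microglia identity, phagocytosis and lysosome, disease-associated microglia, Alzheimer risk loci, IFNG response, type I interferon response, NF-kB inflammatory genes, MHC class I and MHC class II antigen presentation, Toll-like receptors and inflammasome, alternative activation and resolution, cell cycle, glycolysis and hypoxia, housekeeping genes, and markers of neurons, astrocytes and oligodendrocytes, endothelium and fibroblasts, lymphocytes, granulocytes with mast and erythroid cells, germ layers and lineages, and liver. TDGF1, ESRG and C1orf43 were not among the protein-coding genes used. A list was set against 10000 random lists of the same size, matched in 20 bins of the covered length summed over both lists. Its median log2 ratio was called above or below when its percentile was at least 97.5 or at most 2.5. The percentile describes these peak lists and is not a p-value. Some genes are in several lists.

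The genes named were chosen by a rule: the transcription factors known to be delivered in this differentiation (among them SPI1, CEBPA, CEBPB, IRF5 and IRF8) and CLYBL; the 10 called genes with the greatest gain and the 10 with the greatest loss in bp, skipping overlapping windows; up to 3 called members of each list with the greatest change in the main direction of that list; members of the pluripotency, microglia identity, IFNG response and NF-kB lists with a gene-end peak in 1 list alone; and the genes at the 5 clusters with the greatest cover in each list. The rule took 205 genes for iPSCs against microglia and 120 for microglia against stimulated microglia, of which the text names a part. Clusters were peaks joined across gaps of up to 12 kb, and the top 15 per list were described.

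The calls were tested on simulated data, with the earlier list of each comparison set against an altered copy of itself. In the copy, 200 genes were lengthened by added cover, 100 of them 2.5-fold and 100 of them 4-fold. In the simulation from the iPSC list, run on 12001 measured genes, 100% of genes lengthened 2.5-fold and 100% of those lengthened 4-fold were called. Of the untouched genes, 1.64% were called. In that from the untreated microglia list, on 15931 genes, the shares were 95%, 100% and 2.80%. The simulated lists dropped 5% of the peaks and moved peak edges by up to 50 bp, so the share of untouched genes called depends on these settings. The added cover exceeded the rule of size by construction, and the copies lack the differences in peak width and total cover of the real lists. The shares therefore check the computation and not the error of the real calls. In the real comparisons, 68.2% of the measured genes were called for iPSCs against microglia and 6.33% for microglia against stimulated microglia.

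Alternatives changed the minimum overlap, the q threshold, the number of peaks per list, the gene window, the gene-end window, the pseudocount, the filter on covered length, the scaling of total covered length, the matching of random lists, the gap for joining peaks and the sequences used. Equal numbers of peaks meant cutting both lists to their peaks of highest −log10 p, at a count well below that of the smaller list. A setting with each peak set to 500 bp around its summit was added after seeing the data. Motif shares were planned and not run, because no genome sequence was used here. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.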

Results

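H3K27ac was profiled in KOLF2.1J iPSCs that carry inducible transcription factors, in the microglia made from them, and in the same kind of microglia after LPS and IFNG. The authors' lists held 77208 peaks in iPSCs, 57380 in microglia and 55347 in stimulated microglia. Peaks on other sequences than the chromosomes used numbered 178, 88 and 89. The iPSC peaks were narrow, with a median width of 550.0 bp, against 1824 bp in microglia and 1842 bp in stimulated microglia. The shortest peak was 140.0 bp long in iPSCs, 577 bp in microglia and 595 bp in stimulated microglia. In total, peaks covered 67.9 Mb in iPSCs, 144 Mb in microglia and 141 Mb in stimulated microglia. The median −log10 q was 9.96, 113 and 82.8, and the median fold over background was 4.01, 5.72 and 4.75. A q above 0.05 was carried by 657, 8 and 19 peaks. No replicate values were given by these lists, so the differences below have no replicate error.

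By number of regions, most distal H3K27ac belonged either to iPSCs or to both kinds of microglia. The union of the 3 lists made 115333 regions. Of these, 50187 were called in iPSCs alone, with a mean length of 816 bp, and 3.59% of them lay at a gene end. A further 29442 regions were called in both microglia lists and not in iPSCs, with a mean length of 2721 bp and 11.4% at a gene end. Because of this difference in length, the counts do not give the share of covered sequence. Nearby peaks that do not overlap also count as separate regions. A −log10 q of at least 10 was held by 49.9% of the iPSC peaks, 93.8% of the microglia peaks and 88.8% of the stimulated peaks. Regions called in all 3 lists numbered 15268, and 58.0% of them lay at a gene end. Untreated microglia alone held 10352 regions and stimulated microglia alone held 8128. Regions shared by iPSCs with a single microglia list were few, at 954 with the untreated and 1002 with the stimulated cells.

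**Figure D1:**
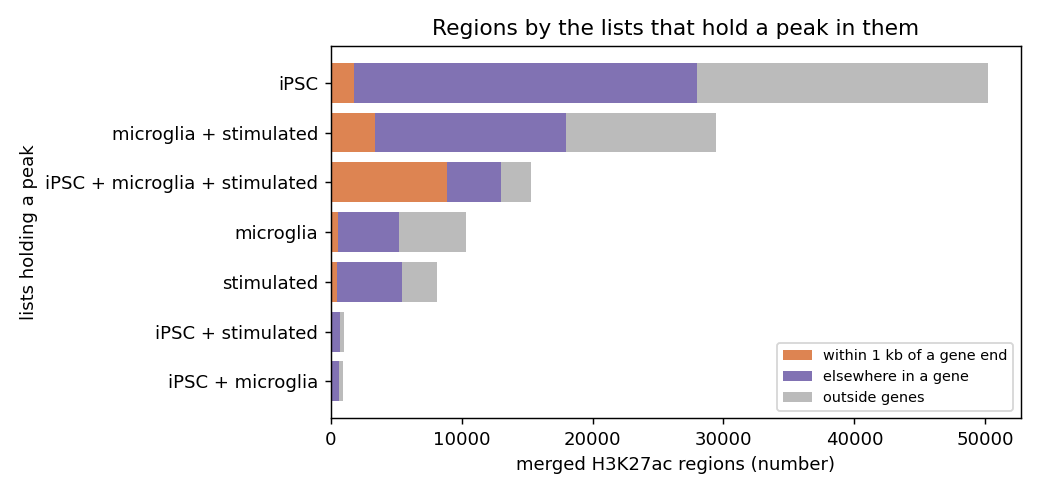
Horizontal bars give the number of merged H3K27ac regions (x axis) for each combination of lists that hold a peak in them (y axis), split by position within 1 kb of a gene end, elsewhere in a gene, or outside genes. The iPSC bar reaches 50187 regions, while the bar of all 3 lists reaches 15268 and has the greatest share at gene ends, 58.0%. Bars count regions whatever their length, and regions of iPSCs alone had a mean length of 816 bp.

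The comparison of iPSCs with day 18 microglia asks how the acetylated landscape differed between the starting cells and the differentiated ones. Pluripotency genes lost cover and myeloid and microglial genes gained it. Of 33 measured pluripotency genes, 24 were shorter in microglia and none (0) was longer, while all 30 myeloid transcription factors and 31 of 33 measured microglia identity genes were longer. POU5F1, which encodes the core pluripotency factor OCT4 (chromosome 6, 31164337 to 31170682), had 10.1 kb under peaks in iPSCs and 1.76 kb in microglia. SPI1, which encodes the myeloid regulator PU.1 (chromosome 11, 47354860 to 47378547), had 0.454 kb in iPSCs and 21.1 kb in microglia. CSF1R, the receptor for the microglial survival factors CSF1 and IL-34 (chromosome 5, 150053295 to 150113365), had 0 kb in iPSCs and 52.0 kb in microglia.

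Across all genes the microglia list covered more sequence. Of 16492 measured genes, 10061 were longer in microglia and 1188 shorter, so that 89.4% of the called genes were longer. After the microglia list was scaled to the total covered length of the iPSC list, 5013 genes were longer and 2466 shorter, a share of 67.0%. The median log2 ratio of all measured genes was 1.39, and 0.38 over the 15314 genes measured after scaling. Scaling shifts a ratio by up to −1.09, and by less where the microglia cover is small. Lists are therefore set against random lists from the same comparison, and counts are given before and after scaling. With each peak set to 500 bp, a setting added after seeing the data, 2608 genes were longer and 3091 shorter. That setting counts peaks more than their length. Among the 205 genes taken by the naming rule, 32 called genes turned direction under it and 41 were no longer called without turning. Turns were counted among called genes alone.

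Named genes of the delivered factors had longer cover in microglia. Reads from inserted copies would map to the exons of these genes, and the lists do not separate them. IRF8, a regulator of myeloid identity, had no peak in its iPSC window (0 kb) and 7.83 kb in microglia. IRF5 rose from 2.71 to 20.5 kb, and CEBPA from 0.424 to 3.43 kb. CEBPB rose from 0.907 to 5.24 kb, although its log2 ratio was −0.58 with peaks set to 500 bp. Its 2 iPSC peaks, of 0.536 and 0.371 kb, lay wholly inside the annotated gene, and the microglia peak was 5.24 kb long. A single peak beyond the higher-coordinate end of SPI1 (chromosome 11, 47386736 to 47402147), nearer to SLC39A13 than to SPI1 and for the most part outside the SPI1 window, had the highest −log10 q of the microglia list, 9389, and the matching peak had the highest of the stimulated list, 8157. At CLYBL, the insertion site (chromosome 13, 99606690 to 99909444), cover fell from 66.2 kb in iPSCs to 12.6 kb in microglia. The direction at CLYBL turned to a log2 ratio of 1.25 when only the 10 kb around the gene ends were used.

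The median log2 ratio of the pluripotency list was −1.95, against 1.45 in its random lists, and its percentile was 0. After scaling, 30 of its 33 measured genes were shorter. LIN28B, an RNA-binding regulator of let-7 microRNAs, fell from 43.8 to 10.97 kb, and SALL2 from 22.6 to 2.16 kb. PRDM14 and GDF3, with 6.25 and 2.85 kb in iPSCs, had no peak in the microglia windows (0 kb). Gene-end peaks were called in iPSCs alone at 12 members, POU5F1, LIN28A, DPPA4, DPPA2, SALL2, PRDM14, FGF2, CDH1, USP44, GDF3, FOXD3 and TET1. LEFTY1 had a gene-end peak in microglia alone. With 50 kb on each side of the gene, POU5F1 turned to a log2 ratio of 0.59.

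Myeloid transcription factors had a median log2 ratio of 3.32 (percentile 100) and microglia identity genes 3.27 (percentile 100), and 23 and 24 of them stayed longer after scaling. RUNX1, a hematopoietic regulator, rose from 0 to 116 kb, ETV6 from 21.5 to 146 kb and MAF from 11.6 to 82.8 kb. Among identity genes, MERTK, a receptor for apoptotic cells, rose from 2.44 to 37.3 kb and TGFBR2 from 18.4 to 53.3 kb, the latter no longer called after scaling. Gene-end peaks appeared in microglia alone at 22 identity genes, among them P2RY12, P2RY13, GPR34, TREM2, C1QA, C1QB, C1QC, ITGAM and CD14. P2RY12, a purinergic receptor used as a marker of homeostatic microglia, rose from 3.78 to 31.7 kb. TMEM119 had no peak in any list (0 kb) and SALL1 was shorter in microglia, at 4.43 kb against 13.9 kb in iPSCs, both named after their values were seen. TREM2, PTPRC, FCER1G, LCP1, TGFBR2 and ETV6 turned direction with peaks set to 500 bp.

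Lists tied to macrophage function also lay above their random lists. The phagocytosis and lysosome list had a median of 3.11 (percentile 100), with 25 of 27 genes longer and 20 after scaling. There, PSAP, the precursor of the saposins, rose from 3.82 to 49.8 kb, LIPA from 23.7 to 83.9 kb and AXL from 7.32 to 50.6 kb. The LIPA window overlaps those of 7 other genes, among them CH25H, IFIT1, IFIT2 and IFIT3. LIPA was no longer called after scaling, and with 500 bp peaks PSAP and LIPA turned to log2 ratios of −0.97 and −0.30. Disease-associated microglia genes had a median of 2.38 (percentile 99.3), with 18 of 21 longer and 0 shorter, against 11 and 1 after scaling, and its percentile was 96.0 with peaks set to 500 bp. ABCG1, a cholesterol exporter, rose from 0 to 46.6 kb and CTSB from 1.31 to 40.3 kb. For genes at Alzheimer risk loci the median was 2.91 (percentile 100), with 24 of 32 longer and 2 shorter, against 19 and 6 after scaling, the longer ones including INPP5D, from 8.54 to 86.1 kb, PTK2B, from 4.07 to 67.8 kb, and TSPAN14, from 4.16 to 50.0 kb. PTK2B had a log2 ratio of −0.13 around its gene ends alone.

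Inflammatory and antigen presentation lists lay above their random lists in untreated microglia. NF-kB inflammatory genes had a median of 3.42 (percentile 100), with 33 of 39 longer and 2 shorter, against 25 and 2 after scaling, and IL1B, a secreted cytokine, rose from 0 to 17.8 kb. Toll-like receptor and inflammasome genes had a median of 3.11 (percentile 100), with 25 of 27 longer and 0 shorter, against 23 and 1 after scaling, among them NLRP3, from 0.225 to 21.3 kb. IFNG response genes had a median of 2.61 (percentile 100), with 30 of 33 longer and 1 shorter, against 18 and 1 after scaling. IDO1, which starts tryptophan breakdown, was the exception that was shorter, from 4.49 to 1.63 kb, and it turned to 0.22 and 0.57 with 5 kb and 50 kb flanks. Type I interferon genes had a median of 2.24 (percentile 99.9), with 20 of 28 longer and 1 shorter, against 16 and 2 after scaling. The MHC class I list had a median of 2.06 (percentile 97.54), with all 18 longer and 11 after scaling, and percentiles of 96.5 with random lists matched on gene length and 95.2 with 1 member kept per window, and the MHC class II list 3.05 (percentile 99.97), with 11 of 12 longer and 9 after scaling. Of the 15 MHC class II genes, 12 were measured. Outside the naming rule, gene-end peaks of that list were called in microglia alone at HLA-DMB, CTSS, IFI30 and LGMN. They were called in iPSCs alone at HLA-DRB1 and HLA-DOA. Alternative activation genes had a median of 2.79 (percentile 99.98), with 17 of 18 longer and 1 shorter, against 12 and 1 after scaling. With 50 kb flanks, the percentiles of the IFNG, type I interferon, MHC class I and MHC class II lists were 97.0, 79.7, 89.3 and 61.985, and with 500 bp peaks those of the type I interferon and MHC class I lists were 88.2 and 95.4.

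Markers of other lineages varied. Granulocyte, mast and erythroid markers lay above their random lists, with a median of 2.57 (percentile 99.9) and 12 of 13 longer, 7 after scaling, and percentiles of 87.6 with 500 bp peaks and 86.2 with 50 kb flanks. ALAS2, of heme synthesis, rose from 1.54 to 15.0 kb, and CSF3R, the receptor for granulocyte colony-stimulating factor, from 1.71 to 12.6 kb. Housekeeping genes had a median of 1.28 (percentile 33.2), with 14 of 21 longer and 4 after scaling. The cell cycle list had a median of 0.83 (percentile 6.70), with 8 of 22 longer and 2 shorter, against 1 and 5 after scaling and percentiles of 1.98 with equal numbers of peaks, 2.21 with 5 kb flanks and 1.81 with matching on gene length, and the glycolysis and hypoxia list 1.32 (percentile 34.2), with 12 of 18 longer and 1 shorter, against 4 and 4 after scaling. Neuron markers had a median of 1.15 (percentile 17.8), with 8 of 15 longer and 6 shorter, against 2 and 6 after scaling. Astrocyte and oligodendrocyte markers had a median of 2.18 (percentile 93.1), with 7 of 13 longer and 4 shorter, against 7 and 5 after scaling, and MBP rose from 4.98 to 93.8 kb. Endothelial and fibroblast markers had a median of 1.37 (percentile 54.7), lymphocyte markers 1.14 (percentile 20.3), germ layer regulators 0.98 (percentile 35.9) and liver markers 2.44 (percentile 89.985), with 9 of 16, 9 of 16, 4 of 9 and 2 of 3 measured genes longer. After scaling, 6, 6, 2 and 2 of these were longer and 4, 3, 3 and 0 shorter. Endothelial and fibroblast markers lay above at 99.01 with a −log10 q of at least 10 and 98.8 with equal numbers of peaks, germ layer regulators below at 1.36 with that q threshold and 1.23 with 5 kb flanks, and neuron markers below at 1.81 with 50 kb flanks and 1.72 with 500 bp peaks. In all, 13 lists lay above and 1 below their random lists.

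**Figure D2:**
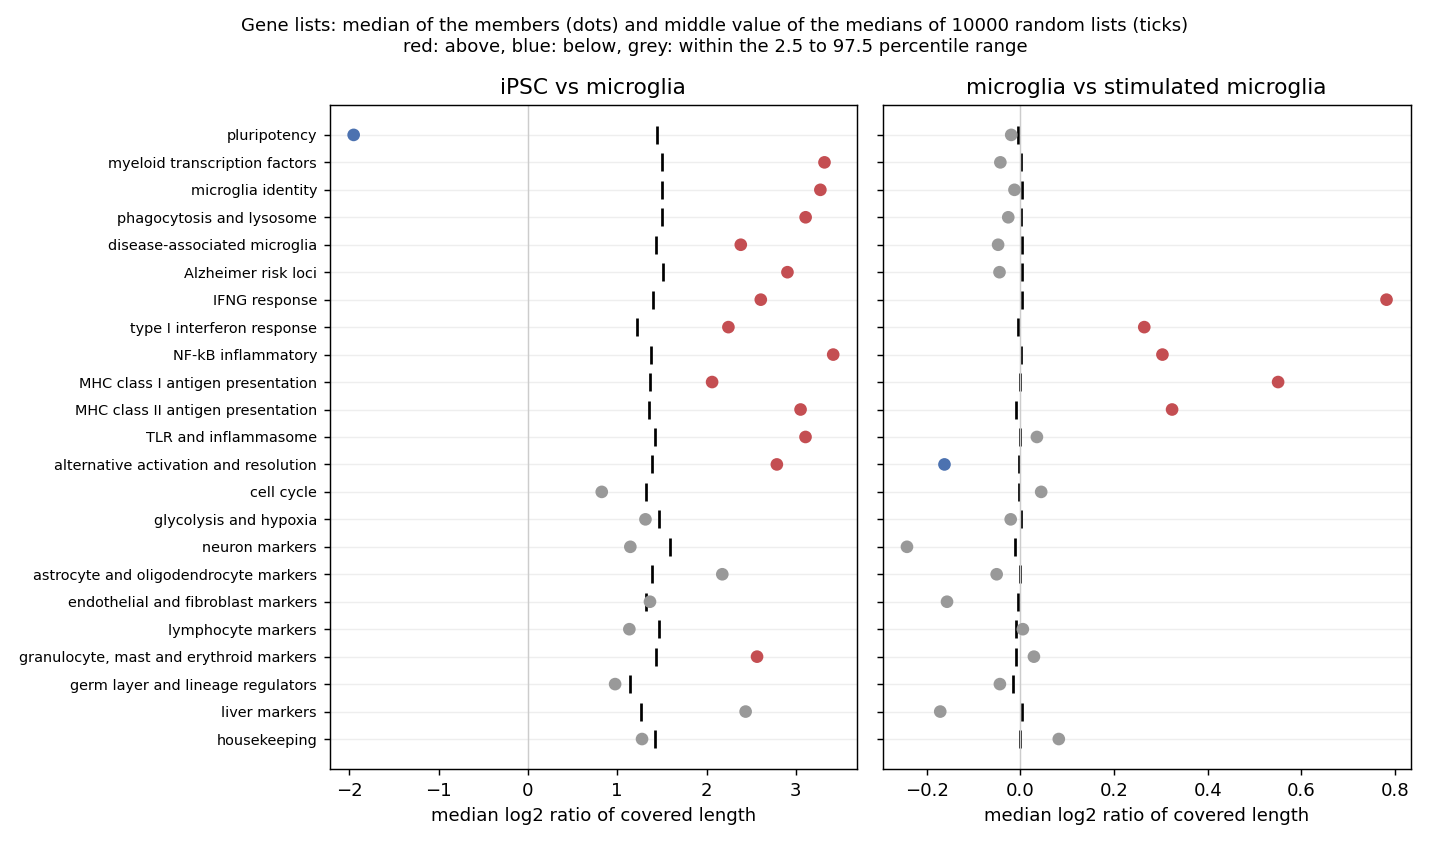
Gene lists stand on the y axis, with each dot the median log2 ratio of covered length of its measured members (x axis, later over earlier condition), and each tick giving the middle value of the medians of 10000 matched random lists. In the left panel 13 lists lie above and the pluripotency list, at −1.95, lies below their random lists, and in the right panel 5 lie above, led by the IFNG response at 0.78.

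The genes with the greatest gain included LPP, from 9.18 to 190 kb, DOCK4, from 13.8 to 167 kb, PLXDC2, from 35.8 to 192 kb, and TNS3, from 4.05 to 124 kb. The greatest losses included the adhesion receptor gene ADGRL2, from 121.1 to 12.4 kb, ANK2, from 98.9 to 3.77 kb, and PTPRZ1, from 74.5 to 0 kb. The cluster with the greatest cover in iPSCs overlapped RBPMS (chromosome 8, 30407924 to 30555812, 74.7 kb covered), and the histone genes of chromosome 6 (26155017 to 26286531) held 68.8 kb. In microglia it overlapped SYNDIG1L, NPC2, ISCA2, LTBP2, AREL1 and FCF1 (chromosome 14, 74469891 to 74714342, 166 kb covered), followed by PLXDC2 with 143 kb. With peaks joined within 5 kb, the greatest cover of a microglia cluster was 105 kb, the length of the cluster at ZNF710 and IDH2. Of the 15 top iPSC clusters, 1 overlapped a top microglia cluster.

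At gene ends, 10330 genes had a peak in both lists, 836 in iPSCs alone and 2900 in microglia alone. Of the iPSC peaks, 32.8% overlapped a microglia peak, and 28.6% of microglia peaks overlapped an iPSC peak, against 6.52% and 6.74% under circular shifts. A reciprocal overlap of at least 50% was met by 5.06% and 6.80%. The shares were 49.1% and 24.2% with a −log10 q of at least 10, and 50.04% and 34.9% with equal numbers of peaks. With 500 bp peaks, 1448 genes had a gene-end peak in iPSCs alone.

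The comparison of untreated with stimulated microglia asks which regions changed with LPS and IFNG. Interferon and antigen presentation lists lay above their random lists, with a part of their genes longer, while the microglia identity and myeloid factor lists lay within the range of theirs. Of 38 measured IFNG response genes, 16 were longer after stimulation and none (0) was shorter. IDO1 (chromosome 8, 39913891 to 39928790) rose from 1.63 to 24.6 kb, and GBP5, an interferon-induced GTPase (chromosome 1, 89256189 to 89272860), from 0 to 6.73 kb. CXCL10, which attracts T cells (chromosome 4, 76021118 to 76023497), rose from 4.55 to 19.8 kb, and its windows are shared with CXCL9 and CXCL11. Among the losses were PDE2A, a cyclic nucleotide phosphodiesterase, from 11.5 to 1.44 kb, and SPP1, which encodes osteopontin, from 2.64 to 0 kb. With at least 3000 bp required, SPP1 was not measured and its call was lost.

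Most genes passed the rule of size in neither direction. Of 16229 measured genes, 449 were longer and 579 shorter, and 489 and 555 after scaling. The median log2 ratio was −0.003. Peaks overlapped at 80.2% of the untreated and 83.4% of the stimulated list, against 9.43% and 9.79% under circular shifts. Peaks called in 1 list alone numbered 11334 in untreated and 9166 in stimulated microglia, with a median −log10 q of 19.5 and 16.2 against 201 and 127 for the shared peaks. With at least 3000 bp required, 248 genes were longer and 231 shorter. The counts were 155 and 140 with a pseudocount of 2000 bp and 289 and 332 with 500 bp peaks. With equal numbers of peaks, a setting that also dropped the weaker peaks of both lists, they were 751 and 735.

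**Figure D3:**
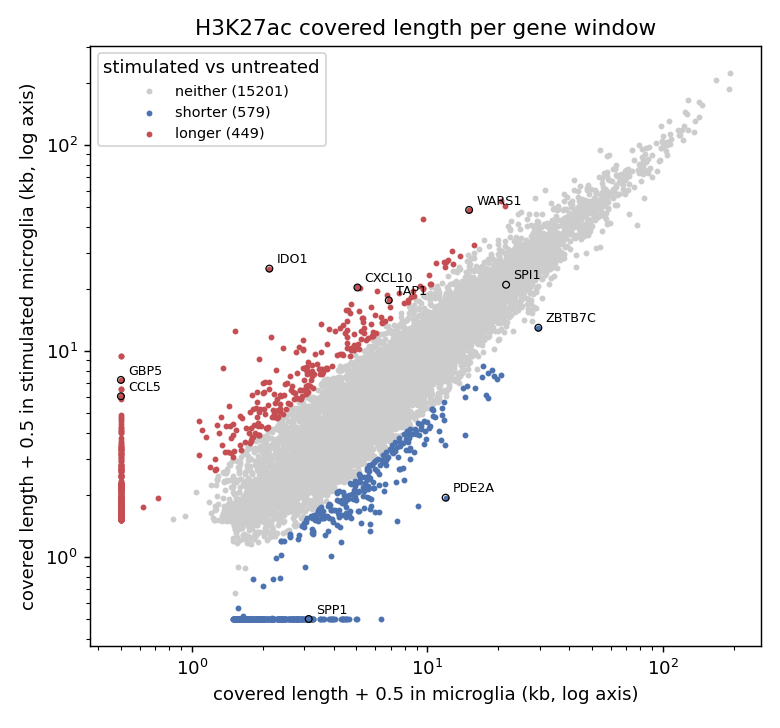
Each point is a measured protein-coding gene, with covered length plus 0.5 kb in untreated microglia on the x axis and in stimulated microglia on the y axis, both log axes, and circles mark labelled genes. The 449 longer genes (red) lie above the diagonal band and include IDO1 and GBP5, while the 579 shorter genes (blue) lie below it.

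The IFNG response list had a median log2 ratio of 0.78, with a percentile of 100, and it stayed above its random lists with 500 bp peaks. WARS1, a tryptophanyl-tRNA synthetase, rose from 14.5 to 47.8 kb, although with 500 bp peaks its log2 ratio was −0.42. Gene-end peaks were called after stimulation alone at GBP1, GBP2, GBP4, GBP5, CXCL9, CXCL10, CXCL11, IL15, IL15RA and ETV7. CXCL9 rose from 4.66 to 19.7 kb and CXCL11 from 1.03 to 11.99 kb. CD274, which encodes the immune checkpoint ligand PD-L1, rose from 9.79 to 20.6 kb. CIITA, the master regulator of MHC class II, had 27.5 kb before and 36.9 kb after and was not called. CD274 and CIITA were outside the naming rule for this comparison, so their own values were not tried under its alternatives. The 36 peaks of the stimulated list alone in the windows of this list had a median −log10 q of 15.8, against 127 for the shared peaks of the stimulated list, and 30.6% of them lay above the median of the list, against 10.8% of the peaks of the stimulated list alone genome-wide.

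Antigen presentation lists lay above their random lists as well. In the MHC class I list the median was 0.55 (percentile 100) and 8 of 18 genes were longer. TAP1 and TAP2, the peptide transporters, rose from 6.36 to 17.1 kb and from 3.98 to 11.7 kb, and PSMB9, of the immunoproteasome, from 4.10 to 15.3 kb, in windows that overlap. The MHC class II list had a median of 0.32 (percentile 99.9) with 3 of 14 longer, among them HLA-DRA, from 1.20 to 3.72 kb. Outside the naming rule, HLA-DRA, HLA-DRB1, HLA-DPB1, HLA-DQA1 and HLA-DOA had gene-end peaks in the stimulated list and not in the untreated one. NF-kB inflammatory genes had a median of 0.30 (percentile 100), with 8 of 40 longer, 10 after scaling. TRAF1 rose from 12.2 to 30.1 kb, TNFAIP2 from 10.4 to 26.1 kb, and NFKB1 from 11.8 to 26.99 kb, the last with a log2 ratio of −0.02 around its gene ends alone. CXCL8, CCL5, TNFAIP6, BIRC3 and CCR7 had gene-end peaks after stimulation alone, and CCL5, a chemokine, rose from 0 to 5.52 kb. Type I interferon genes had a median of 0.26 (percentile 100), with 4 of 31 longer, including IFI44L, from 0 to 2.68 kb. With 500 bp peaks, a count of peaks, these 4 lists tied with their random lists, as most lists of this comparison did.

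**Figure D4:**
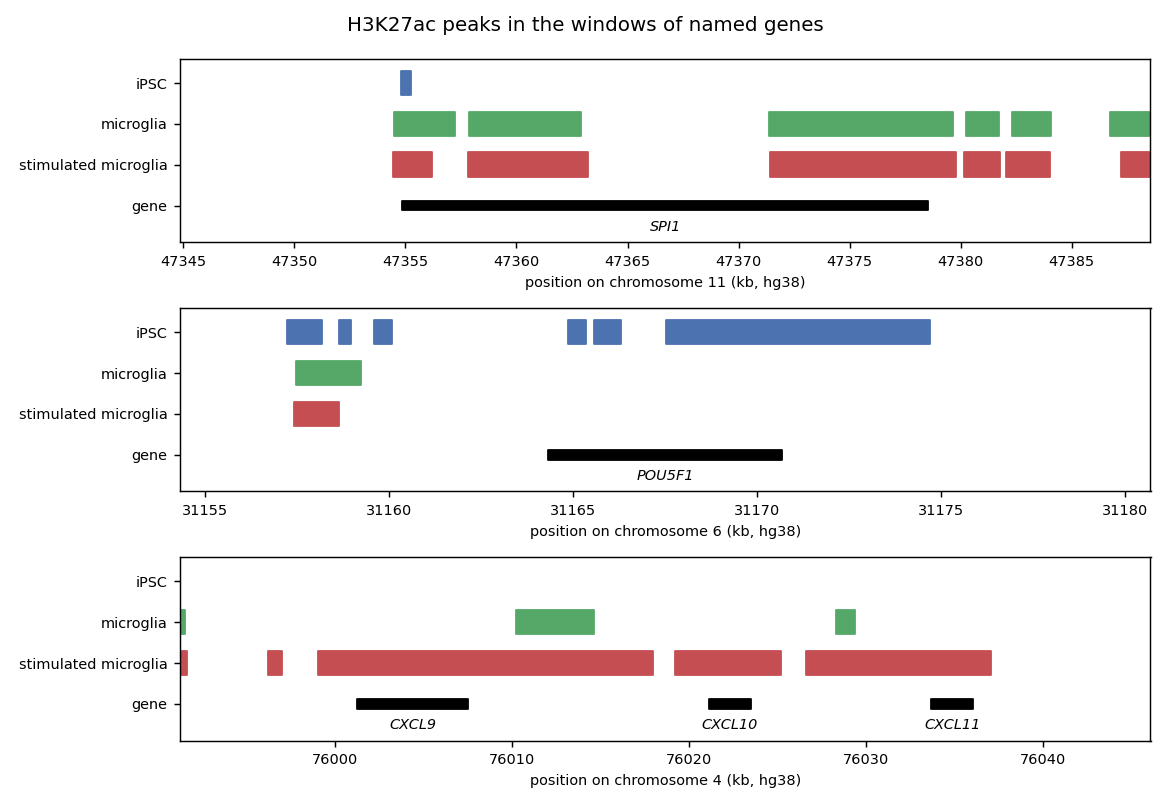
Coloured bars are H3K27ac peaks of each list along hg38 positions in kb (x axis) in the windows of SPI1, POU5F1 and the neighbours CXCL9, CXCL10 and CXCL11, clipped at the window edges, and black bars are the annotated genes. The 7.15 kb iPSC peak across one end of POU5F1 is absent from both microglia lists, SPI1 has 0.454 kb in iPSCs and 21.1 kb in microglia, and CXCL10 has 4.55 kb before and 19.8 kb after stimulation.

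Few cell identity genes passed the rule of size. Myeloid transcription factors had a median of −0.04 (percentile 15.4), with 1 of 30 called, TAL1, shorter from 9.16 to 4.09 kb. Microglia identity genes had a median of −0.01 (percentile 35.9), with 1 of 33 called, the complement gene C1QB, longer from 9.11 to 19.8 kb and at −0.42 with 500 bp peaks. With a pseudocount of 2000 bp, 17 of the 120 named genes of this comparison were no longer called, among them TAL1, C1QB and HLA-DRA. SPI1 had 21.1 kb before and 20.4 kb after, IRF8 7.83 and 7.47 kb, IRF5 20.5 and 17.9 kb, CEBPA 3.43 and 2.68 kb, CEBPB 5.24 and 7.03 kb, and CLYBL 12.6 and 13.9 kb, none of them called. Phagocytosis genes had a median of −0.03 (percentile 26.1, and 2.35 with 50 kb flanks) with 0 of 27 called, Alzheimer risk loci −0.04 (percentile 13.9, and 0.26 with equal numbers of peaks) with 1 of 31 longer, CD2AP, and disease-associated microglia genes −0.05 (percentile 16.7) with 2 of 21 shorter, LPL and SPP1. Toll-like receptor genes had a median of 0.04 (percentile 76.8) with 0 of 27 called. Alternative activation genes were the list below its random lists, with a median of −0.16 (percentile 1.70), although 0 of 17 passed the rule of size, and the percentile was 7.30 with equal numbers of peaks, 9.80 with 5 kb flanks and 3.56 with 500 bp peaks.

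The other lists lay within the range of their random lists under the settings chosen first. Percentiles were 38.3 for pluripotency, 80.1 for cell cycle, 35.0 for glycolysis and hypoxia, 90.7 for housekeeping, 2.61 for neuron markers and 26.9 for astrocyte and oligodendrocyte markers. They were 3.87 for endothelial and fibroblast, 58.6 for lymphocyte, 70.0 for granulocyte, mast and erythroid, 39.6 for germ layer and 14.5 for liver markers. Neuron markers lay below at 0.90 with a −log10 q of at least 10 and at 1.75 with 5 kb flanks, and with 50 kb flanks endothelial and fibroblast markers lay below at 1.78 and housekeeping genes above at 98.1. In these lists 0 to 2 genes were longer and 0 or 1 shorter. FGF2 and FOXD3 of the pluripotency list were longer after stimulation, from 0 to 2.22 kb and from 0.928 to 2.72 kb. With at least 3000 bp required, neither was measured. Both, with LIN28A, had a gene-end peak after stimulation alone, while SFRP2 of that list had one in untreated microglia alone. By −log10 q, the gene-end peak of LIN28A lay at percentile 9.31 of the stimulated list, that of FGF2 at 29.3 and that of FOXD3 at 62.8. In all, 5 lists lay above and 1 below.

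Gains among the greatest in bp were also at IDO2, from 20.8 to 50.1 kb in a window that overlaps that of IDO1, GCH1, the entry enzyme of tetrahydrobiopterin synthesis, from 15.2 to 32.3 kb, IKBKE, from 11.2 to 26.5 kb, and DRAM1, from 13.3 to 28.5 kb. ART3 gained from 9.05 to 43.2 kb in a window that holds CXCL10 and CXCL11. The greatest losses included ZBTB7C, from 29.1 to 12.5 kb, GABRA3, from 20.1 to 7.10 kb, and LTBP1, from 13.9 to 3.40 kb. RBM47 (chromosome 4, 40404783 to 40632768) and PLXDC2 held the top clusters after stimulation, with 165.238 and 165.231 kb covered. With peaks joined within 5 kb, the greatest cover of a stimulated cluster was 123.5 kb, the length of the one at LYN. Of the 15 top microglia clusters, 10 overlapped a top cluster of the stimulated list. Gene-end peaks were shared by 12804 genes, with 426 in untreated microglia alone and 295 in stimulated microglia alone, and 461 in the latter with 500 bp peaks. Of the iPSC peaks, 32.9% overlapped a peak of the stimulated list and 29.7% of its peaks overlapped an iPSC peak, close to the values of untreated microglia.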

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

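The housekeeping test was chosen only after the result was seen, and the 500 bp setting was added after seeing the data.

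Long noncoding RNA loci away from the windows of protein-coding genes entered no comparison of the report, and 7218 of them were examined. For each list, the 3 with the greatest gain in cover over its comparison list are given, with that list in place of a control. In iPSCs, LOC101927421 (chromosome 5, 125036831 to 125367734) had 44.1 kb against 2.34 kb in microglia, LINC01122 (chromosome 2, 58520753 to 59063766) 36.6 kb against 0 kb, and MIR924HG (chromosome 18, 39206924 to 39751995) 35.5 kb against 7.97 kb. In microglia, LINC02964 (chromosome 8, 125519907 to 125680134) had 57.6 kb against 0 kb in iPSCs, LINC00607 (chromosome 2, 215611563 to 215843536) 59.7 kb against 9.47 kb, and LOC101928004 (chromosome 6, 6694792 to 6801171) 44.4 kb against 2.97 kb. In stimulated microglia, LINC02541 (chromosome 6, 113623535 to 113650075) had 19.6 kb against 10.95 kb in untreated microglia, LOC107984859 (chromosome 16, 11210935 to 11224964) 11.7 kb against 5.06 kb, and LINC01258 (chromosome 4, 38420662 to 38523180) 13.8 kb against 7.18 kb. These loci were picked for their difference, and no replicate values exist to test it.

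Most genes had longer cover in microglia than in iPSCs, and a difference in peak calling or depth may account for much of this. Housekeeping genes had a median log2 ratio of 1.28. Resampling the 21 genes gave a bootstrap range of 0.98 to 1.82, a spread among genes and not a replicate error. The housekeeping median was close to the 1.39 of all measured genes. Ribosomal protein genes did not share this match, with a median of 0.58 over 80 genes against 1.41 in their random lists. With each peak set to 500 bp, the median of all genes was −0.17, but equal widths turn cover into a count of peaks, of which iPSCs had more, so this leaves the part of interval width undecided. At a fold of 4.5 to 5.5, the median −log10 p was 5.43 times as high in microglia peaks as in iPSC peaks, as more reads behind the microglia list would give. The shortest microglia peak was 4.12 times as long as the shortest iPSC peak, so the calling settings may differ too. These values do not tell depth from calling settings. A true spread of acetylation with the change of cell type stays open, since no read-level signal was analysed here.

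Peaks called in 1 microglia list alone may in part be peaks near the calling threshold in both lists. The median −log10 q of the stimulated peaks alone lay at percentile 20.2 of their list, and that of the untreated peaks alone at 17.6. At IFNG response genes the 36 peaks of the stimulated list alone lay at percentile 19.7, while 30.6% of them lay above the median of the list, against 10.8% of stimulated peaks alone genome-wide. A −log10 q of 10 or more was held by 69.4% of the 36 peaks, 68.9% of the stimulated and 82.1% of the untreated peaks alone, well above the lowest values of the lists, 0.729 and 0.870. For the peaks called in 1 list alone, a response to LPS and IFNG stays open beside the threshold, as weak new peaks would look the same. Stimulated peaks that overlapped any untreated peak were left out here, so these values do not bear on gains by wider peaks. Examples are an 18.9 kb stimulated peak at CXCL10, with a −log10 q of 3985, and a 17.0 kb peak at IDO1, with 4137.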

How the results depend on the processing

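Setting each peak to 500 bp was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each list combines the replicates of its condition and no value per replicate was used here, so leave-one-out was not possible either. Motif shares were not run for lack of a genome sequence, and the alternative on start sites was run on gene ends. The peak lists give no read depth, so signal below their thresholds cannot be seen. With a −log10 q of at least 5, no called gene list changed its call in either comparison. The percentile of the IFNG response list with stimulation ranged from 99.8 to 100 over its alternatives. A named gene counted as unchanged when it kept its call and direction, or had no call in both settings, whatever its sign. Of the 205 named genes of iPSCs against microglia, 161 were unchanged after scaling and 129 with 500 bp peaks. With a −log10 q of at least 10, 201 were unchanged. Of the 120 of untreated against stimulated microglia, 120, 80 and 117 were unchanged. With equal numbers of peaks, 198 of the 205 and 98 of the 120 were unchanged, and with 50 kb flanks 189 and 100. The counts were 197 and 103 with a pseudocount of 2000 bp, and 196 and 106 with at least 3000 bp covered.

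Peak overlap of iPSCs with microglia (32.8% and 28.6%) moved to 30.8% and 11.8% with at least 50% of the peak covered, 5.06% and 6.80% with reciprocal overlap, 38.7% and 26.5% with −log10 q of at least 5, 49.1% and 24.2% with at least 10, 50.04% and 34.9% with equal numbers, and 19.1% and 23.3% with 500 bp peaks. That of untreated with stimulated microglia (80.2% and 83.4%) moved in the same order to 78.8% and 81.9%, 74.1% and 76.8%, 79.5% and 84.1%, 77.9% and 85.4%, 84.1% and 84.4%, and 74.6% and 77.4%. Stricter overlap lowers overlap by construction. For the other changes the cause was not tested.

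In iPSCs against microglia, gene-end peaks in iPSCs alone were 1448 with 500 bp peaks. Longer and shorter genes were 2608 and 3091 with 500 bp peaks and 5013 and 2466 after scaling, and shorter genes were 790 with a pseudocount of 2000 bp. Lists below were 2 with −log10 q of at least 10, equal numbers, 500 bp peaks, 50 kb flanks or gene-length matching, and 3 with 5 kb flanks, and lists above were 8 with 50 kb flanks. In untreated against stimulated microglia, gene-end peaks after stimulation alone were 461 with 500 bp peaks. Longer and shorter genes were 751 and 735 with equal numbers, 289 and 332 with 500 bp peaks, 155 and 140 with a pseudocount of 2000 bp, and 248 and 231 with at least 3000 bp covered. Lists below were 2 with −log10 q of at least 10, 0 with 500 bp peaks and 3 with 50 kb flanks, and 1 list lay above with 500 bp peaks, where most lists tied with their random lists. With peaks joined within 5 kb, the greatest cover of a microglia cluster was 105 kb, the length of the cluster at ZNF710 and IDH2 in place of the one at LTBP2, and that of a stimulated cluster was 123.5 kb, the length of the one at LYN. A larger pseudocount, a stricter filter and a shorter gap lower these counts by construction. For the rest the cause was not tested.

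With 500 bp peaks, which count peaks and not length by construction, these log2 ratios of iPSCs against microglia turned: CEBPB −0.58, ETV6 −0.16, ZMIZ1 −0.32, TGFBR2 −0.63, LIPA −0.30, PSAP −0.97, IFI35 −0.45, TAPBP −0.73, IL4R −0.14, MCM5 −0.18, CCND2 −0.84, E2F1 −0.20, PKM −1, HK2 −0.46, SLC17A7 −0.50, CD79A −1, TREM2 −0.58, PTPRC −0.51, FCER1G −0.42, LCP1 −0.42, FCGR1A −0.42, SYNDIG1L −1.42, NPC2 −1.58, ISCA2 −1, AFF1 −0.88, PLD2 −0.43, GP1BA −1.58, SLC25A11 −1, RNF167 −1, SPAG7 −0.74, CAMTA2 −0.47 and QTRT1 −0.74. IDO1 turned to 0.22 with 5 kb and 0.57 with 50 kb flanks, POU5F1 to 0.59 with 50 kb flanks, and SPAG7 to −0.0035 after scaling. Around gene ends, CLYBL turned to 1.25, PRKG1 to 1.961 and PTK2B to −0.13. With stimulation, WARS1 and C1QB turned to −0.42 with 500 bp peaks, INA to 0.032 and COL1A2 to −0.10 with 50 kb flanks, and NFKB1 to −0.020 around gene ends. Turns were looked for among called genes alone. Beyond the 500 bp setting, the cause was not tested.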

Other observations

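The gene families below were grouped by symbol beyond the fixed lists, and the named members were chosen after their values were seen. In iPSCs against microglia, 24 of 41 families (58.5%) lay outside the range of their random lists. All 12 measured SIGLEC genes, receptors for sialic acid, were longer in microglia with a median log2 ratio of 3.53, as were all 10 LILR genes with a median of 3.68. Chemokines were longer at 26 of 30 genes, S100 genes at 16 of 19 and cathepsins, lysosomal proteases, at 12 of 14. Core and linker histone genes lay below their random lists with a median of −0.32 over 75 genes, of which 10 were longer and 2 shorter, and ribosomal protein genes with 0.58 over 80 genes, of which 25 were longer and 1 shorter. Contactins and neurexins, neural adhesion genes, had a median of −0.40, with 7 of 16 shorter and 2 longer, and SOX factors −0.06, with 7 of 16 shorter and 6 longer. The family counts were not recomputed after scaling. APOBEC3, protocadherin, MS4A and TNF families were no longer outside with 1 member per window.

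In untreated against stimulated microglia, 18 of 42 families (42.9%) lay outside. Guanylate binding proteins, interferon-induced GTPases, were longer at 5 of 6 genes with a median of 3.24. The APOL family was longer at 3 of 5 genes, with APOL3 at 6.41 kb before and 15.8 kb after, and the APOBEC3 family at 3 of 7, with APOBEC3A at 2.18 and 5.78 kb. Metallothioneins, which bind zinc and copper, were longer at 3 of 9 genes, MT1M from 1.41 to 3.98 kb, MT1A from 0 to 2.30 kb and MT1H from 0 to 1.51 kb. IL32 was longer, from 1.68 to 11.2 kb, while the chemokine genes CCL24 and CCL14 fell from 4.52 and 4.01 kb to 0 kb. Potassium channels lay below with 10 of 69 shorter and 3 longer, and contactins and neurexins with 3 of 15 shorter and 1 longer. SIGLEC genes had a median of −0.32, with 1 of 12 shorter, SIGLEC8, from 5.08 to 1.98 kb. HOX clusters and chemokine receptors were among the families no longer outside with 1 member per window. Members of a family share windows and regulation, so the share of families outside is not a test of independent groups.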
